A study of Mus musculus with 2 samples.

How the data were processed

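The series holds 2 libraries, 1 for the GFP control virus and 1 for the Ikzf2 virus, placed in these groups by the treatment label. They were made from sorted tdTomato-positive cochlear cells with a droplet 3' kit. Per the submitters' processing notes, Cell Ranger 2.0.2 was used, with no role given. The aligner and its settings are not given in the sources used here.

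The file analysed was the authors' deposited gene annotation in GTF layout, a table of the whole series that holds genome positions in bases and text fields. Per the file headers, it follows assembly GRCm38 with patch 4 and a gene build updated in 2016, and the authors added 4 gene models with the source CUSTOM. It held 1511492 rows and 5 header lines. The gene rows had 3 biotypes only, and how other biotypes were removed is not given in the sources used here. The file holds 0 columns of per-sample values. Depth and its precision therefore concern no value here. With 1 library per group no test between the groups was possible in any case, and the comparison of GFP with Ikzf2 expression that had been set down in advance was not analysed here.

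Transcripts, exons, coding sequence and 3' UTRs were read from the annotation. Coding lengths include the stop codon. The 3' window of a gene was the last 500 exonic bases of each of its transcripts. A window was called shared when an exon of another gene on the same strand overlapped it by at least 1 base. The longest 3' UTR over the protein-coding transcripts of a gene was its 3' UTR length, and a gene with no annotated 3' UTR had no value. Lists of outer hair cell, inner hair cell, general hair cell, supporting cell and other cell type markers, 80 genes in all, were fixed before the data were examined, from general knowledge of the cochlea. So were the tests, the alternatives marked as planned and the rule for named genes. That rule took every added gene, Myo15, the Ikaros family and, from each list, genes with a shared window and the 3 genes with the longest and the 3 with the shortest 3' UTR. One gene that the rule names is not reported here.

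Shared windows were compared between the outer and inner hair cell lists with a two-sided Fisher's exact test, and 3' UTR lengths with a two-sided permutation test of the difference of medians (100000 resamples). Each list was also placed among 10000 random lists of the same size from the protein-coding genes, as a mid-percentile. For 3' UTR lengths, only genes with an annotated 3' UTR were counted and drawn. The random lists were not matched on expression. Genes are not replicates of an experiment, so these tests describe the lists and not cells or animals.

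GENCODE release M21, also on GRCm38, served as a second annotation. Of the 27998 mouse gene identifiers, 27722 (99.0%) were found there, 27716 of them on the same chromosome and strand. The same start and end were found for 21763 (78.5%) of the 27722 genes. All 86430 transcripts with the same identifier and version, of 93562 here, had identical exons, so positions were compared directly. Transcripts with another version or no match in M21 were not part of that check. Its transcript sequences were used to look for near-identical copies of the last 500 bases of the list and Ikaros family genes with BLAST+ 2.17.0 (identity of at least 95% over at least 100 bases, same orientation). Of these 84 genes, 75 could be searched. The other 9 had no protein-coding transcript of the same version and length in both annotations. The copies and all comparisons with M21 were added after the data were examined.

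The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. They were tested on simulated data first. All 200 simulated genes got the right answer for a shared window and for 3' UTR length. The permutation test called 4 of 100 pairs of lists with no difference and 91 of 100 with a true difference. That simulated difference was several-fold, larger than the one found between the hair cell lists. How often a difference of the observed size would be called was not simulated. The alternatives tried were windows of 200 and 1000 bases, an overlap of at least 100 bases, protein-coding partners or transcripts only, either strand, the median 3' UTR, mean log10 lengths, merged 3' ends and the M21 models.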

Results

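The series compared 2 single-cell libraries from mouse cochleae at postnatal day 8. One came from cochleae given a control virus that carries GFP, and the other from cochleae given a virus that carries Ikzf2, which encodes Helios, a zinc finger transcription factor of outer hair cells. Both viruses used Anc80, an engineered adeno-associated virus capsid. The animals carried Myo15-Cre and the Ai14 reporter, in which Cre recombinase removes a stop cassette so that hair cells make the red fluorescent protein tdTomato. Cells with tdTomato were sorted before capture on a droplet platform that sequences the 3' ends of transcripts. There was 1 library per group, with no replicate.

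The values analysed here come from the gene annotation of the series, a mouse annotation with added viral and reporter genes. It holds gene positions and no measurement of either library. The expression of the GFP and Ikzf2 libraries, their depth, their cell numbers and the change between them were not analysed here, and no statement below concerns them. What follows describes which reporter, viral and hair cell genes the annotation holds and how their 3' ends are drawn. All positions are on mouse assembly GRCm38.

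The annotation held 27998 mouse genes with 93562 transcripts, of which 22048 were protein-coding, 3707 were long intergenic non-coding RNAs and 2243 were antisense genes. They lay on 22 chromosomes, the mitochondrial one included, and 19 scaffolds. Another 4 genes, on 3 added sequences, described the reporter and the viruses. The sequence named for the Ai14 reporter carried FloxedStop, a model of the stop cassette, from base 1 to 622 and tdTom, the tdTomato reporter, from base 623 to 2274. FloxedStop had the biotype protein-coding but no coding sequence. The models Anc80_EGFP (814 bases) and Anc80_Ikzf2 (1726 bases) each lay on an added sequence of their own. All 4 had a single exon on the plus strand.

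The tdTom, Anc80_EGFP and Anc80_Ikzf2 models were annotated with a start codon, a coding sequence and a stop codon; their base sequences were not used here. The annotated length of tdTom corresponds to 476 amino acids in 1431 bases from base 739 to 2169, and that of Anc80_EGFP to 239 amino acids in 720 bases from base 42 to 761. The length of Anc80_Ikzf2 corresponds to 545 amino acids in 1638 bases, from base 50 to 1687. Its 3' UTR was 39 bases long, against 53 bases for Anc80_EGFP and 105 bases for tdTom. Of the last 500 bases of each model, 92.2% were coding sequence in Anc80_Ikzf2, 89.4% in Anc80_EGFP and 79.0% in tdTom. These values describe where the models end. Where the viral and reporter transcripts themselves end, and where their reads fall, was not tested.

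The identifiers of the viral Ikzf2 model were not uniform. Its gene row had the identifier Ikzf2, which is the symbol of the mouse gene, whereas its other 7 rows had Anc80_Ikzf2. The symbol on its gene row was Anc80_Ikzf2, and the mouse gene has the identifier ENSMUSG00000025997. How the mixed identifiers affect counting was not tested. The other 3 added genes had 1 identifier each on every row. The exon rows of FloxedStop and tdTom had no gene symbol.

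The comparison of the viral with the mouse Ikzf2 model bears on which Ikzf2 models can be told apart by their annotated 3' ends. Mouse Ikzf2 (ENSMUSG00000025997) lay on the minus strand of chromosome 1 from 69531214 to 69687245 and had 9 transcripts, 7 of them protein-coding and 2 with a retained intron. Of these, 6 reached the same stop codon, at 69538768 to 69538770. Ikzf2-001, with 8 exons, coded for 526 amino acids and had a 3' UTR of 7554 bases, 193.7 times the length of the 3' UTR in the viral model. Among the 19943 protein-coding genes with an annotated 3' UTR, 125 had a longer one.

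The other 5 transcripts with the stop codon ended nearer to it than Ikzf2-001 did. Ikzf2-005 had a 3' UTR of 731 bases and Ikzf2-003 one of 186 bases, while Ikzf2-006, Ikzf2-007 and Ikzf2-009 ended at the stop codon itself. The models of the latter 3 held coding sequence only, so they do not show where such transcripts end. The remaining 3, Ikzf2-010, Ikzf2-004 and Ikzf2-002, ended upstream and did not reach it. The gene had 7 distinct annotated 3' ends, of which 4 lay at or beyond the stop codon. The last 500 bases of Ikzf2-001 and Ikzf2-005 held no coding sequence. In Ikzf2-001 they began 7054 bases beyond the stop codon. In Ikzf2-003, 314 of the last 500 bases were coding, and in the 3 transcripts that ended at the stop codon all 500 were. These lengths are properties of the models and have no sampling error.

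**Figure D1:**
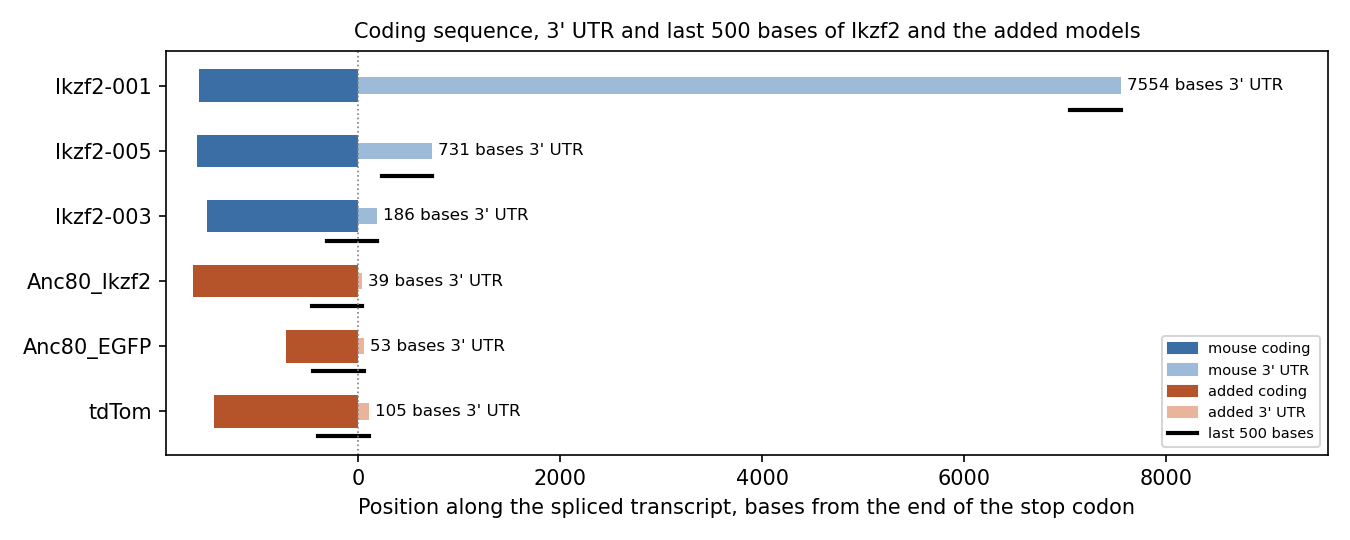
Coding sequence (thick bars), 3' UTR (thin bars) and last 500 bases (black lines) of the 3 mouse Ikzf2 transcripts with a 3' UTR and of the 3 added models with a coding sequence, against the position along the spliced transcript in bases from the end of the stop codon. The 3' UTRs of Ikzf2 run from 186 to 7554 bases, and those of the added models from 39 to 105 bases.

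The viral coding sequence was longer than that of each mouse transcript. It exceeded Ikzf2-001, with 1581 coding bases, by 57 bases or 19 codons, and Ikzf2-005, with 1599 coding bases, by 39 bases or 13 codons.

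Of the other Ikaros family genes, which encode related zinc finger factors, Ikzf1 on chromosome 11 (11685003 to 11772926) had a longest 3' UTR of 3345 bases. The value was 3205 bases for Ikzf4 on chromosome 10 (128630843 to 128645991), 2985 bases for Ikzf5 on chromosome 7 (131388652 to 131410521) and 2084 bases for Ikzf3 on chromosome 11 (98464902 to 98546031). All 4 were shorter than the longest of Ikzf2. An exon of Pstk, on the opposite strand, lay in the last 500 bases of Ikzf5 transcripts.

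Which marker genes of outer and inner hair cells have an unshared 3' end was examined next. All 80 genes of 5 cell type lists were present under their symbols. Sharing was judged by position only. Anc80_Ikzf2 lies on a sequence of its own, so the counts cannot show whether it and mouse Ikzf2 share sequence. None of the 15 outer hair cell genes and none of the 15 inner hair cell genes had an exon of another gene on the same strand within the last 500 bases of a transcript (two-sided Fisher's exact test, p = 1, the only value that counts of 0 can give). The count was also 0 of 18 for hair cell genes of both types, 0 of 14 for supporting cell genes and 0 of 18 for genes of other cell types. Together this was 0 of 80, with an exact 95% upper limit of 4.51%, against 3.24% of all protein-coding genes (714 of 22048). A list of 15 with no shared gene stood at percentile 30.2 of 10000 random lists, one of 18 at percentile 27.5 and one of 14 at percentile 31.2. No list can hold fewer than 0 shared genes, so these mid-percentiles come from ties alone and depend only on list size.

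Myo15, the myosin gene whose promoter drives Cre in these animals, lay on chromosome 11 from 60469339 to 60528369 on the plus strand. It had 5 transcripts with 3 distinct 3' ends and a longest 3' UTR of 944 bases. No other gene had an exon in its last 500 bases on either strand.

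The outer hair cell genes spanned a wide range of 3' UTR lengths. Ikzf2 had the longest at 7554 bases, followed by Bcl11b, a zinc finger transcription factor gene, at 4997 bases and Strip2 at 2773 bases. Chrna9, a subunit of the acetylcholine receptor of hair cells, had the shortest at 79 bases. Ocm, which encodes the calcium buffer oncomodulin, had 272 bases and Lmod3, a leiomodin gene, 311 bases. The median of the 15 genes was 1189 bases, with quartiles of 578.5 and 2159 bases. That median stood at percentile 80.6 of 10000 random lists.

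Among the inner hair cell genes, the solute carrier gene Slc7a14 had the longest 3' UTR at 6218 bases. Brip1, a DNA helicase gene, had 3291 bases, and Slc17a8, the vesicular glutamate transporter of inner hair cells, had 2296 bases. Nacad had the shortest at 72 bases, Fgf8, a growth factor gene, had 192 bases and Cabp2, a calcium-binding protein gene, had 204 bases. Fcrlb had no annotated 3' UTR. The median of the other 14 genes was 967.5 bases, with quartiles of 303.5 and 1714 bases, at percentile 62.8 of random lists. The outer hair cell median was 221.5 bases above the inner one, a difference within the spread of the genes (two-sided permutation test with 100000 resamples, p = 0.676). Its sign turned to -117.75 bases when the median rather than the longest 3' UTR of each gene was used (permutation p = 0.780).

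The 18 hair cell genes of both types had a median longest 3' UTR of 828.5 bases, at percentile 47.0. Myo6, an unconventional myosin gene, had 3858 bases, Pcdh15, a tip link protocadherin gene, 3665 bases and Rbm24, an RNA-binding protein gene, 1773 bases. The shortest were those of Tmc2, a gene of the mechanotransduction channel, at 228 bases, Lhfpl5, whose product belongs to the same complex, at 305 bases, and Ush1c, the harmonin gene, at 372 bases.

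The 14 supporting cell genes had a median of 1280.5 bases, at percentile 86.2. The transcription factor gene Prox1 had 5185 bases, the cell cycle inhibitor gene Cdkn1b 3439 bases and the glutamate transporter gene Slc1a3 2008 bases. Otoa, the otoancorin gene, had 166 bases, S100a1, a calcium-binding protein gene, 294 bases and Hes5, a Notch target gene, 696 bases.

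The 18 genes of other cell types that a sort could hold had a median of 1006.5 bases, at percentile 67.5. The longest belonged to the potassium channel gene Kcnj10 at 4025 bases and the myelin gene Mbp at 3935 bases. The shortest belonged to the haemoglobin genes Hba-a1 at 74 bases and Hbb-bt at 132 bases and to the pigment cell gene Dct at 239 bases. Of the 75 list and Ikaros family genes searched, these 2 haemoglobin genes had a 3' end with a near-identical copy among the transcripts of other genes in GENCODE M21. The added models were not part of that search, so Ikzf2 was not compared with Anc80_Ikzf2 by sequence. The last 500 bases of Hba-a1 matched Hba-a2 at 99.8% identity over 500 bases. Those of Hbb-bt matched Hbb-bs at 100% over 291 bases.

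**Figure D2:**
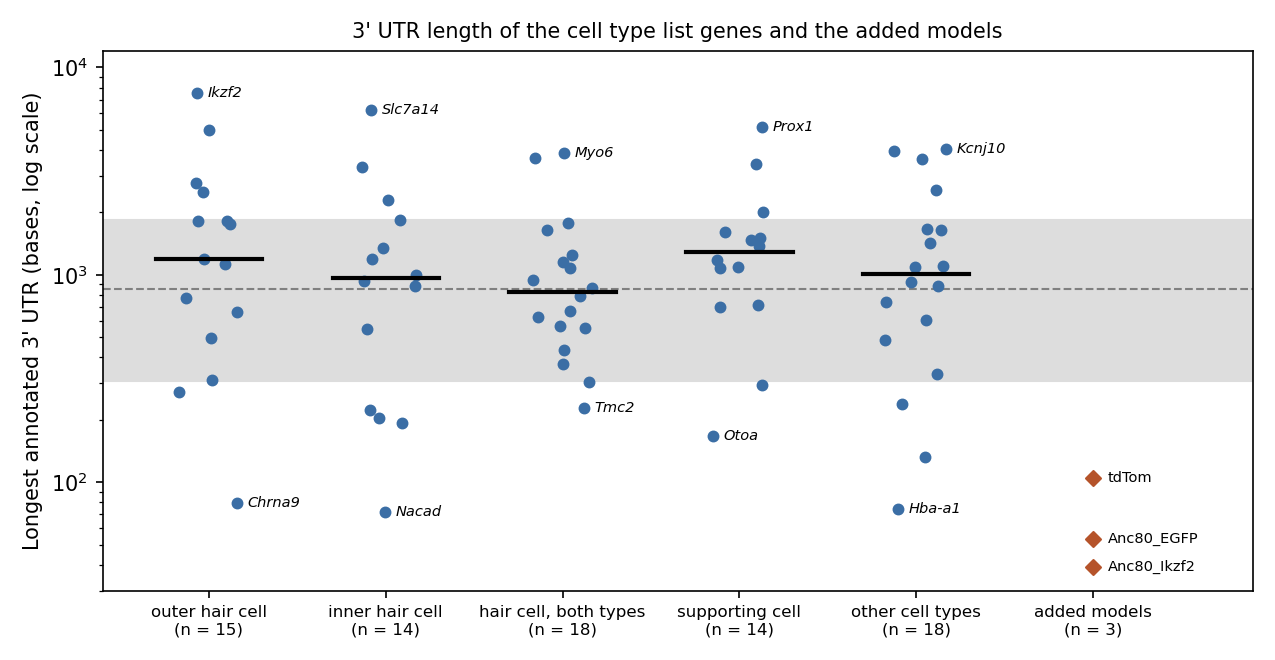
Longest annotated 3' UTR in bases (log axis) of each list gene (points) and each added model with a coding sequence (diamonds). Black bars are list medians. The dashed line is the median (851 bases) of all protein-coding genes with an annotated 3' UTR. The grey band spans their quartiles (308 and 1834 bases). The list medians lie between 828.5 and 1280.5 bases, and the added models lie below the lower quartile at 39 to 105 bases.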

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

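The M21 alternatives were chosen after seeing the data and the others before. The count of list genes with a shared 3' window stayed at 0 of 80 with windows of 200 and 1000 bases, with an overlap of at least 100 bases, and with protein-coding partners or transcripts only. It rose to 3 when either strand counted, with Dnajc5b, Cib2 and Epyc, and to 2 with the M21 models of all biotypes, with Tectb and Cd74, whose windows overlapped microRNA genes. The 5 genes are named because of their values. These partners are absent under the main setting by its construction. The comparison of shared windows between the outer and inner hair cell lists shows nothing about stability, because the counts were 0 of 15 in both under 6 of the 7 alternatives and 0 against 1 with either strand, where Fisher's exact test can only give p = 1. The difference in 3' UTR length missed the 0.05 threshold under all 4 of its alternatives (permutation p from 0.492 to 0.780). Its sign reversed to -117.75 bases with the median 3' UTR of each gene, and the cause was not tested. Leaving out genes with a shared window removed no gene, so that alternative shows nothing. The number of distinct annotated Ikzf2 3' ends was 7, or 6 when ends within 100 bases were merged. No paired analysis was possible because each group has 1 library and no values per library were analysed. For the same reason no alternative was run for GFP against Ikzf2 expression, and no replicate could be left out.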

Other observations

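The comparisons with other protein-coding genes, the M21 comparisons and every test in this part were chosen after the lists had been examined. The isoform test was set up after its result was seen, and the other tests of explanations before theirs. Kcnma1, Tubb3, Calb2 and the M21 values of Lhfpl5 are named because of their values.

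Later 3' end models touched few of the list genes. In GENCODE M21, 68 of the 79 list genes with a 3' UTR had the same longest 3' UTR as here, and 3 differed by over 20 bases. Kcnma1, the large-conductance potassium channel gene of mature inner hair cells, had 7730 bases in M21 against 1197 bases here. Its outermost protein-coding 3' end nevertheless lay at the same place in both. Lhfpl5 had 599 against 305 bases, and its outermost protein-coding 3' end lay 2086 bases further out. Tubb3, a neuronal tubulin gene, had 391 against 333 bases, with its outermost protein-coding 3' end unmoved. Calb2, which encodes the calcium buffer calretinin, had nearly equal 3' UTRs (546 and 545 bases), but a protein-coding transcript in M21 ended 5037 bases further out.

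The coding sequence of Anc80_Ikzf2 was longer than that of mouse Ikzf2. An unaltered copy of another annotated isoform is argued against, since the smallest difference in coding length to a mouse Ikzf2 transcript of either annotation was 39 bases. Lengths alone cannot speak against an isoform with added codons. An upstream in-frame start codon is argued against for Ikzf2-001, Ikzf2-005 and Ikzf2-003: the number of these with an open start codon at the place that the viral length needs was 0. The other 3 transcripts with the stop codon had no annotated sequence upstream and were not searched. Added codons such as a tag, or a coding sequence from another source, may remain as candidate explanations and were not tested, because the viral sequence was not used here.

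List genes less often had an exon of an opposite-strand gene in their 3' window than the other protein-coding genes: 3.75% (3 of 80, exact 95% interval 0.780 to 10.6%) against 11.6% (Fisher's exact p = 0.0224, Benjamini-Hochberg adjusted 0.0347 over 3 such comparisons). The same comparison on the same strand gave 0% against 3.25% (exact p = 0.117, adjusted 0.117). A candidate explanation is that clone-named gene models carry the background overlaps. With these left out of both sides, the background stood at 8.67% and the lists at 1.25% (1 of 80, interval 0.0316 to 6.77%), so such models do not account for all of the difference. That well-studied genes were picked for the lists stays open as an untested explanation. For the same-strand windows, 6.73% of random lists of 80 held no shared gene, so the count of 0 is not beyond chance. With clone-named and readthrough-like models left out this share was 0.2968, which cannot decide, since the full background already allowed 0.

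A 3' end over 100 bases further out in M21 was found for 2 of 80 list genes (2.50%, exact 95% interval 0.304 to 8.74%) against 10.1% of the other protein-coding genes (Fisher's exact p = 0.0231, adjusted 0.0347). With clone-named genes and genes without an annotated 3' UTR left out, the background fell to 6.62%, within the interval of the lists (0.308 to 8.85%, 2 of 79). This met the prediction of the hypothesis that less well annotated genes carry the moved 3' ends. The lists still stood lower, at 2.53% (Fisher's exact p = 0.175). The interval is too wide for this test to decide whether such genes account for the difference.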
